A study of Mus musculus with 12 samples.

How the data were processed

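Expression was measured in whole testes of C57BL/6N mice at 2 weeks of age with Affymetrix whole-transcript arrays, 1 array per testis and 12 in all. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase and purified on RNeasy columns, and biotin-labelled targets were made with the Affymetrix WT PLUS reagent kit. The groups were taken from the labels as 3 Sox3 knockout testes (KO), 3 Sox3-Sox2KI testes (KI), 3 WT littermates of KI mice and 3 WT littermates of KO mice, with arrays named by group and by the replicate number of the labels. The labels call the replicates biological and the design text calls the mutant testes independent.

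The deposited values were log2 expression values per transcript cluster (0.9149 to 13.93) for 41345 clusters. RMA, Affymetrix Expression Console and Partek 6.6 are named per the submitters' processing notes, with no role for each. The background correction, filters and annotation release the authors used are not given in the sources used here. RMA sets arrays to a common distribution, which leaves relative changes within an array, so a fall of many abundant germ cell transcripts can raise others in relative terms. Clusters were named from the platform annotation, in which 23521 clusters had 1 gene symbol, 1814 had several and 16010 had none. A gene with over 1 such cluster (1082 genes) was represented by the cluster of highest mean over the 12 arrays, which gave 22180 genes. Of these, 21994 were matched by Entrez gene number to a table of mouse genes on the GRCm38.p6 assembly, used for chromosomes and older symbols. No genome or probe sequence was used here, so probe positions within Sox3 and Sox2 were not known, and a cluster shared by near-identical genes could not be split. No coordinates are given.

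The main test was limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 on the deposited values, with all 12 arrays in 1 fit of 3 genotype groups and Benjamini-Hochberg adjustment over 22180 genes at 0.05. No filter on dim genes was applied. The comparison of WT litters and the difference of the mutant effects within litter origin came from a fit with the 4 label groups. Sox3, Sox2 and Sox1 were also tested with exact two-sided permutation tests over all 84 splits (20 for littermates) in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Depth was judged from signal, since arrays give no counts. The 1105 olfactory receptor genes measured, most of which are silent in most tissues, had a median of 3.29 and a 95th percentile of 5.33, against a median of 6.27 over all genes, and served as a background.

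The 20 gene lists were SoxB1 and related SOX genes, stem-enriched undifferentiated spermatogonia, committed progenitor spermatogonia, differentiating spermatogonia, early meiotic prophase, pachytene and later meiosis, spermatid genes, pan-germ cell genes, replication-dependent histone genes, the retinoic acid pathway, proliferation, p53 targets and apoptosis, and markers of Sertoli cells, Leydig cells, peritubular and smooth muscle cells, interstitial fibroblasts with extracellular matrix, endothelium, macrophages and immune cells, erythroid cells, and the epididymis. They were written, with the design, the tests, the alternatives and the rule for named genes, before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives, adjusted over the 20 lists. List tests with another normalization, filter, weighting, covariate, fewer arrays or controls of the other litter origin used the preset correlation only. Some lists share genes, such as Tex101 in the differentiating and pan-germ cell lists.

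The rule for named genes took Sox3, Sox2 and Sox1. For each mutant comparison it took the 10 largest increases and 10 largest decreases among genes that passed, or the 10 genes of smallest p where fewer than 10 passed. For the other comparisons it took 5 genes in each direction. From each list with a member past the threshold it took up to 4 members of smallest p, and otherwise up to 2 members of highest level. The values of 1 gene that the rule took are not reported here by name. Values of these genes in comparisons that did not name them, and the X-linked, Leydig and small nucleolar RNA genes of the closing observations, were chosen after their values were seen.

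The fits were tested on simulated data made from the deposited values, with 200 genes of 22180 changed by known amounts in each of 5 runs. For KO against 6 WT testes 52.8% of genes changed 1.41-fold and 96.5% of those changed 2-fold were recovered, and for KO against 3 littermates 22.8% and 94.0%. Between 4.2% and 6.4% of calls were false. The noise was drawn independently for each gene, so these rates leave out the correlation among genes and the structure among arrays. The alternatives were median centring, a new quantile normalization, a filter keeping genes above the median level, every named cluster in place of 1 per gene, an intensity trend with robust variance, array quality weights, a fold limit of 1.5, leaving out each array in turn, the replicate number as a block, control arrays from 1 litter origin, 9 or 6 arrays in the fit, litter origin as a covariate, and other set tests. A fit with the pachytene list mean of each array as a covariate, and a histone list widened by clusters that name several histone genes, were added after seeing the data. Clusters with no or several symbols were left out of the comparisons.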

Results

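The series asked how SoxB1 genes act in the developing mouse testis. Sox3, an X-linked member of the SoxB1 transcription factors that is known from spermatogonia, was knocked out with CRISPR/Cas9 in one line (KO). In the other line, named Sox3-Sox2KI (KI), Sox2, a close relative of Sox3, was knocked into the Sox3 locus. Whole testes were taken at 2 weeks of age, when the first wave of spermatogenesis has reached meiosis. RNA of each testis was measured on its own Affymetrix whole-transcript array, in C57BL/6N mice. There were 12 arrays, made up of 3 KO testes, 3 KI testes, 3 WT littermates of the KI mice (WT 1, WT 2 and WT 3) and 3 WT littermates of the KO mice (WT 4, WT 5 and WT 6). Each mutant was compared with all 6 WT testes, the mutants with each other, and the WT testes of the KI litters with those of the KO litters. The number of arrays limits the precision. The median 95% interval over the 22180 genes reached 0.22 to either side of the log2 change for either mutant against WT, and 0.26 for KI against KO and for the WT litters. Array medians lay between 5.74 and 5.82 on the log2 scale.

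Sox3 was lower in KO testes. Its level was 7.28 ± 0.06 (SD, n = 6) in WT and 6.61 ± 0.04 (SD, n = 3) in KO testes, a change of -0.68 on the log2 scale (SE 0.09, 95% interval -0.88 to -0.48). This was a 1.6-fold lower level (limma adjusted p = 0.0161), and the exact two-sided permutation p was 0.0238, the smallest that the 84 splits of these arrays allow. Against the KO littermates alone the change was -0.69, with an exact p of 0.1, the smallest that 20 splits allow. The positions of the array's probes within Sox3 were not known here, so a remaining signal of 6.61, above the 95th percentile of the olfactory receptor genes (5.33), says nothing of intact transcript. In KI testes Sox3 was 6.99 ± 0.26 (SD, n = 3), a difference of -0.30 from WT that did not pass the adjusted test (adjusted p = 0.945, exact p = 0.0952). The array labelled KI 1 lay within the WT range of 7.21 to 7.36 with a Sox3 level of 7.26, while KI 2 was at 6.75 and KI 3 at 6.95. Without the array labelled KI 1 the KI difference was -0.44.

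The Sox2 signal was close to background in every testis. It was 4.04 ± 0.17 (SD, n = 6) in WT, 4.12 ± 0.10 (SD, n = 3) in KO and 4.33 ± 0.18 (SD, n = 3) in KI testes, all under the 95th percentile of the olfactory receptor genes, which served as a background. The positions of the probes within Sox2 were not known either, so this signal says nothing of the level of the inserted gene. The KI difference of 0.29 did not pass (adjusted p = 0.945, exact p = 0.0714). The WT arrays of the KI litters (4.15 to 4.22) lay above those of the KO litters (3.81 to 3.94), and against its own littermates alone KI Sox2 was higher by 0.14 (exact p = 0.3, where 0.1 is the smallest possible). Against the KO littermates, KO Sox2 was higher by 0.23, with all 3 KO arrays above them (exact p = 0.1). Sox1, the remaining SoxB1 gene, was 5.10 in WT, 5.12 in KO and 5.15 in KI testes, under the same limit (exact p = 0.857 and 0.429). Of the 5 measured members of the list of SoxB1 and related SOX genes, Sox3 fell in KO testes and the other 4 did not pass, also when adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.343, median change 0.02, mean change -0.083). In KI testes it did not pass among all genes (adjusted p = 0.691), was lower among genes above the median level (adjusted p = 0.0499, median -0.154), and 1 member, Sox3, was lower when adjusted over the list alone. The list above the median level of 6.27 leaves out Sox2 and Sox1, whose mean levels were 4.13 and 5.12. It therefore rests on few genes, the targeted Sox3 among them.

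**Figure D1:**
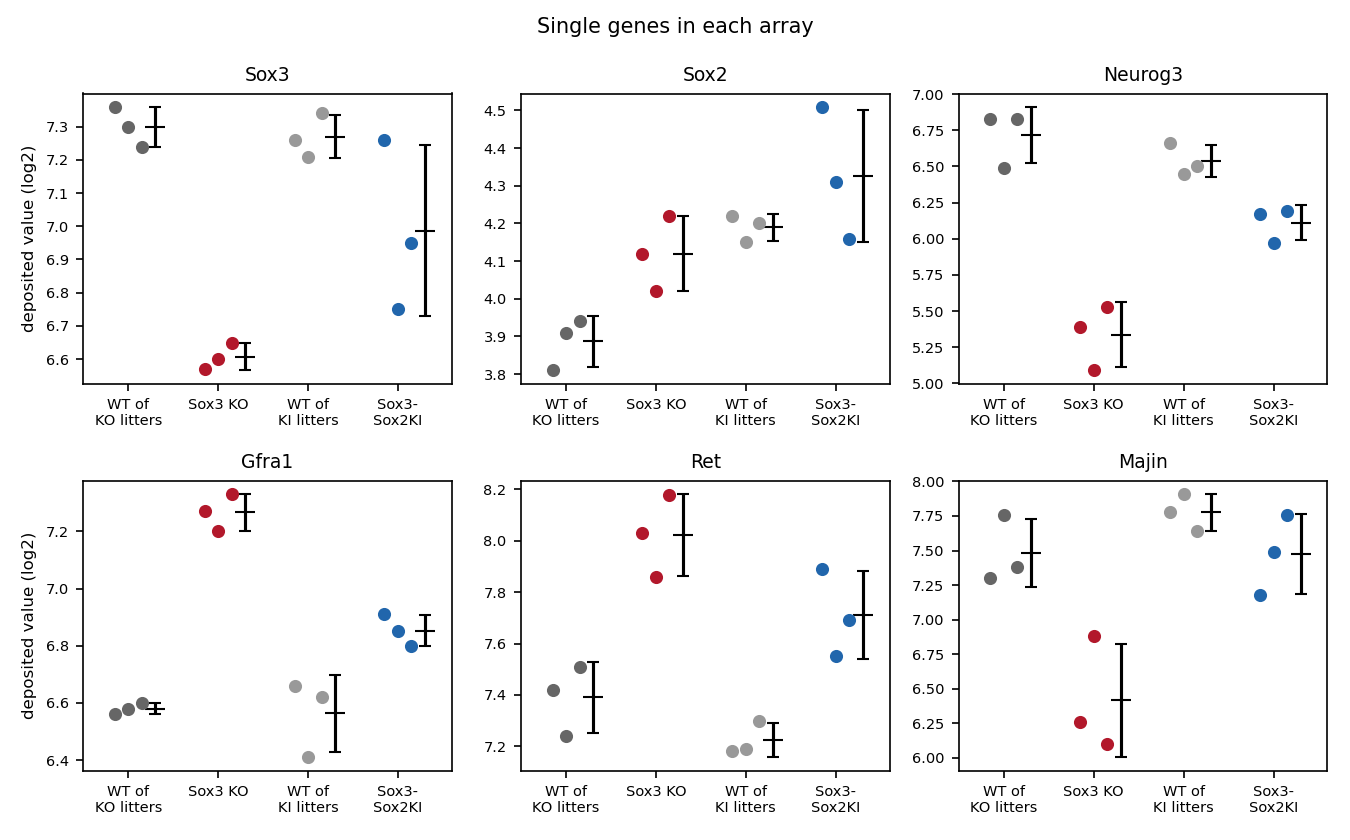
Deposited log2 values of Sox3, Sox2, Neurog3, Gfra1, Ret and Majin in each of the 12 arrays, in the 4 label groups, with the mean and SD of the 3 arrays beside each group. The KO arrays lie outside the range of all WT arrays for every gene but Sox2, and the KI arrays lie between WT and KO for Neurog3 (5.97 to 6.19) and Gfra1 (6.80 to 6.91).

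KO testes differed from WT in many genes. Neurog3, a transcription factor of spermatogonia committed to differentiate, fell 2.45-fold, from 6.63 ± 0.17 (SD, n = 6) in WT to 5.34 ± 0.22 (SD, n = 3) in KO testes (adjusted p = 0.00181). The KO level lies at the background limit of 5.33, so the size of this fall is not fixed and background signal may hide part of it. Gfra1 and Ret, which encode the co-receptor and the receptor through which GDNF sustains spermatogonial stem cells, rose 1.62-fold and 1.64-fold, to 7.27 and 8.02 (adjusted p = 0.00207 and 0.0161). As lists, genes of meiotic prophase, later meiosis and cell division fell by camera with a preset correlation, and genes of stem-enriched spermatogonia and of several somatic cell types rose. Of these only cell division held with the correlation estimated (adjusted p = 0.0139 with an estimated correlation), and the smallest value of the others was 0.0808. By fry, the other planned set test, each list called by camera passed except that of interstitial fibroblasts (0.0591). The fry adjusted p was 0.00299 for early meiotic, 0.0165 for pachytene and 0.000448 for stem-enriched genes. In all, 558 genes rose and 520 fell among 22180 (limma, adjusted p under 0.05), of which 75 rose and 240 fell by at least 1.5-fold. All 3 KO arrays lay outside the range of the 6 WT arrays for 2541 genes (11.46%, where chance gives 2.38%), and this held for 906 of the 1078 genes that passed.

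The largest decreases included genes known from spermatocytes. Fabp9, a fatty acid binding protein of germ cells, fell 8-fold (SE 0.73 on the log2 scale, adjusted p = 0.0397). Cers3, a ceramide synthase for very long acyl chains, changed by -2.43 and Kctd19, a nuclear protein of spermatocytes, by -2.40. Gm10505 (-2.20), 1700102P08Rik (-2.13), 1700020N01Rik (-2.09), Gm1096 (-2.05), the heat shock factor family member Hsf5 (-1.98), Poteg (-1.98) and 1700029M20Rik (-1.96) completed the 10 largest decreases. For each of these 10 genes at least 1 KO array lay within the WT range. Fabp9, for example, was 7.85 to 10.75 in WT and 8.59 in KO 2, with KO 1 at 5.69 and KO 3 lower still. The largest increases were Sel1l3 (1.33), Socs2 (1.05), an inhibitor of cytokine signalling, the adhesion receptor Adgrl3 (0.99), Shisa8 (0.98), Mirlet7c-1 (0.93), the arginine deiminase Padi2 (0.92), Myoz2 (0.91), the receptor Erbb3 (0.88), the interferon-induced GTPase Irgm1 (0.86) and Ildr2 (0.83). The WT levels of Adgrl3 (5.08), Mirlet7c-1 (4.81) and Irgm1 (5.29) and the KO level of Poteg (5.15) lie under the background limit, so the sizes and ranks of these 4 changes are not fixed. Background signal can hide part of a change, and the sizes also moved with the arrays used. With 1 array left out Irgm1 changed by 0.55 to 1.06, Mirlet7c-1 by 0.76 to 1.21, Adgrl3 by 0.95 to 1.06 and Poteg by -2.42 to -1.7.

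Genes of early meiotic prophase fell as a group in KO testes by camera with a preset correlation (adjusted p = 1.13e-27). The call was lost with the correlation among them estimated from the data (adjusted p = 0.0808 with an estimated correlation). Of 36 measured members 25 fell, none rose and 11 did not pass, and all 36 changes were negative, with a median of -0.595. Adjusted over the list alone, 29 fell. Majin, which attaches telomeres to the nuclear envelope, changed by -1.22 (SE 0.19, adjusted p = 0.0204). The recombination helicase Hfm1 (-1.12) and the synaptonemal complex protein Syce3 (-0.88) fell as well. The mean of the list was between 7.54 and 8.13 in the KO arrays and between 8.31 and 8.58 in the WT arrays.

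Genes of pachytene and later meiosis had a median change of -0.83 in KO testes. Of 29 members 12 fell, none rose and 17 did not pass, and 22 fell when adjusted over the list alone. Ybx2, a germ cell RNA-binding protein, fell 2.83-fold (adjusted p = 0.032). Brdt, the testis bromodomain protein (-1.30), the sperm gene Tsga10 (-1.07) and Mybl1, the transcription factor of pachytene spermatocytes (-0.87), fell as well. The list fell by camera (adjusted p = 2.33e-14), but not with an estimated correlation (adjusted p = 0.155 with an estimated correlation). Its mean also varied among WT testes, from 6.70 in WT 6 and 6.85 in WT 4 to 7.68, and KO 2, at 6.81, lay within that range. The pan-germ cell list fell too (adjusted p = 6.2e-11, and adjusted p = 0.0808 with an estimated correlation), with 12 of 34 members down, none up, 22 not passed and a median of -0.355. Adjusted over the list alone, 19 fell and 1 rose. The surface protein Tex101 (-1.10), the Tudor proteins Rnf17 (-0.69) and Tdrkh (-0.59) of the piRNA pathway and the helicase Ddx43 (-0.51) were among those that fell. Of the 21 spermatid genes none passed, over all genes or when adjusted over the list alone, and the list did not pass (adjusted p = 0.357, median 0.009, mean -0.033). The spermatid list mean lay between 5.33 and 5.48 in all arrays, close to the background limit of 5.33, so the absence of a call says little. The list members Odf1 and Odf2, of the sperm tail, changed by 0.27 and -0.48 (adjusted p = 0.0786 and 0.0872).

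**Figure D2:**
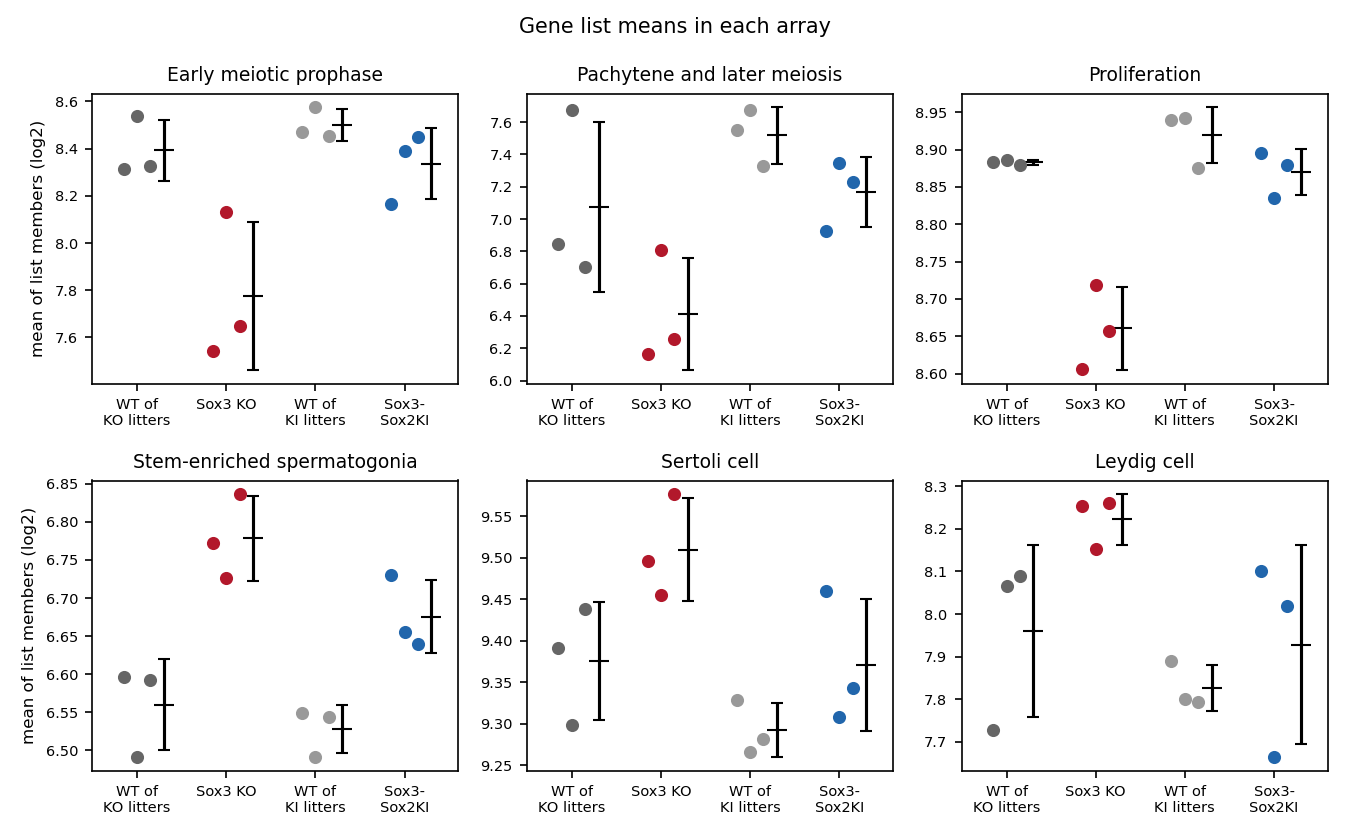
Mean log2 value over the members of 6 gene lists in each of the 12 arrays, in the 4 label groups, with the mean and SD of the 3 arrays beside each group. The early meiotic (7.54 to 8.13) and proliferation (8.61 to 8.72) means of the KO arrays lie below those of all WT arrays, while the pachytene mean of KO 2 (6.81) lies within the WT range.

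Some spermatogonial genes rose and others fell in KO testes, and most did not pass. In the stem-enriched list of undifferentiated spermatogonia 6 of 20 members rose, none fell and 14 did not pass, with 10 rising when adjusted over the list alone. Beside Gfra1 (0.70, SE 0.07) and Ret (0.71, SE 0.10), the transcription factor Foxc2 (0.52) and the adhesion molecule Mcam (0.40) rose. The median change was 0.255, and the 3 KO means (6.73 to 6.84) lay above all WT means (6.54 ± 0.05, SD, n = 6). The list rose by camera (adjusted p = 0.000183) but not with an estimated correlation (adjusted p = 0.0808 with an estimated correlation). Its median lay among those of the Sertoli (0.165), peritubular (0.198), fibroblast (0.218) and Leydig (0.301) lists. The list rise therefore cannot be told apart from a relative rise of transcripts outside meiosis. Among 15 genes of committed progenitors, Neurog3 fell (-1.29, SE 0.12), Cdh1, which encodes E-cadherin, rose (0.56) and 13 did not pass, and the list as a whole did not pass (adjusted p = 0.357, median 0.152, mean 0.034). Adjusted over the list alone, 3 rose and 1 fell. Of the 15 members of the differentiating spermatogonia list, Kitl and Uchl1 among them, 3 fell, 2 rose and 10 did not pass. With adjustment over the list alone 6 were down and 3 up. Whether each member is expressed only in these cells was not tested. The protease gene Prss50 (-0.78), Tex101 (-1.10) and the X-linked homeobox gene Esx1 (-0.35) fell, and the DNA methyltransferase Dnmt3a rose (0.31). The list fell with a median of -0.154 (camera adjusted p = 0.0253), and the call was lost with the correlation estimated (adjusted p = 0.245 with an estimated correlation), as it was without WT 4 (0.0742), WT 6 (0.0604) or KO 3 (0.139). It was also lost with a new quantile normalization (adjusted p = 0.058), among genes above the median level (0.0855), with array quality weights (0.0534) and with the WT of the other litter origin as control (0.141).

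Cell division genes fell in KO testes, and this was the list whose call held with an estimated correlation. Of 27 proliferation genes 10 fell, none rose and 17 did not pass, and 18 fell when adjusted over the list alone. The kinetochore kinase Bub1 (-0.58), the topoisomerase Top2a (-0.48), the spindle motor Kif11 (-0.28) and the replication helicase subunit Mcm3 (-0.27) fell. The median was -0.228, and the 3 KO means (8.61 to 8.72) were below all WT means (8.88 to 8.94). The test gave an adjusted p of 2.71e-13 (adjusted p = 0.0139 with an estimated correlation). Of 26 replication-dependent histone genes 4 fell, 1 rose and 21 did not pass, over all genes, and 4 fell and 4 rose when adjusted over the list alone. Those that fell included the germ cell variants H2bc1 (-0.77) and H2ac1 (-0.32) and the linker histone H1f1 (-0.38), while H2bc21 rose (0.37). As a list they did not pass among all genes (adjusted p = 0.164, median -0.025), while among genes above the median level the list fell (adjusted p = 0.00748, median -0.246). Of 21 retinoic acid genes 2 fell, 1 rose and 18 did not pass, with 4 down and 4 up when adjusted over the list alone. The retinal reductase Rdh11 (-0.76) and the retinol carrier Rbp4 (-0.28) fell and Cyp26b1, which degrades retinoic acid, rose (0.39). The retinoic acid list did not pass against all WT (adjusted p = 0.175, median -0.087), and it was lower against the KO littermates alone by camera (adjusted p = 0.0426, and adjusted p = 0.216 with an estimated correlation). With the pachytene list as a covariate, a fit added after seeing the data, the retinoic acid (adjusted p = 0.000645) and histone (0.0418) lists were lower.

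Genes of somatic testis cells rose in KO testes by camera, with adjusted p of 0.0014 (Leydig), 0.000695 (Sertoli), 0.00488 (peritubular) and 0.000755 (interstitial fibroblast). None of these lists held with the correlation estimated (in that order, adjusted p = 0.127, 0.315, 0.245 and 0.429 with an estimated correlation). By fry the Leydig (0.00305), Sertoli (0.0125) and peritubular (0.00659) lists passed and the fibroblast list did not (0.0591). In the fit with the pachytene covariate none of them passed (in the same order, adjusted p = 0.0729, 0.387, 0.308 and 0.96, with medians of 0.09, 0.058, 0.067 and 0.051). The Leydig cell list had a median of 0.301, with 1 of 16 members, the steroid dehydrogenase Hsd3b1 (0.63, SE 0.15), past the test over all genes and 15 not passed. Adjusted over the list alone, 9 rose and 1 fell. Of 28 Sertoli cell genes 2 rose, the inhibin subunit Inhbb (0.38) and the FSH receptor Fshr (0.36), none fell and 26 did not pass, with a median of 0.165 and 11 up when adjusted over the list alone. In the peritubular and smooth muscle list 1 of 16 members rose, Cald1 (0.31), and 15 did not pass, with a median of 0.198 and 6 up when adjusted over the list alone. In the interstitial fibroblast list Dlk1 (0.72) and Pdgfra (0.56) rose and 14 of 16 members did not pass, with a median of 0.218 and 3 up when adjusted over the list alone.

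The remaining lists did not pass in KO testes, and none of their members passed over all genes or when adjusted over the list alone. The 19 p53 target and apoptosis genes had a median of 0.141 (adjusted p = 0.153; Ei24 0.10, Sesn2 -0.18). The 14 endothelial genes had a median of 0.109 (adjusted p = 0.175), with Cdh5 at 0.31 and Eng at 0.27. The 17 macrophage and immune genes (median 0.104, C1qb 0.18, Mrc1 0.04), the 4 measured erythroid genes (median 0.159, Ermap 0.21, Slc4a1 0.11) and the 16 epididymis and efferent duct genes (median 0.106, Esr1 0.32, Cldn3 0.06) each had an adjusted p of 0.343. The erythroid (4.67 to 5.04) and epididymis (4.85 to 5.16) list means lay under the background limit of 5.33 in all arrays, so these results say little. Without KO 2 the endothelial list rose (adjusted p = 0.0172), and without KO 1 the histone list fell (adjusted p = 0.0479).

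How many genes passed in KO testes rested on single arrays and on the choice of control. The count of 1078 became 3 without KO 1, 2323 without KO 2, 2 without KO 3, 36 without WT 1, 35 without WT 2, 18 without WT 3, 32 without WT 5, 1748 without WT 6, 608 without KI 2 and 463 without KI 3, and with the 3 KO littermates alone as control it was 2, Neurog3 (-1.38) and Gfra1 (0.69). Neurog3 and Gfra1 passed in each of the 12 fits that left out 1 array (largest adjusted p = 0.0231 and 0.0277), and Ret, Sox3, Adgrl3 and Ildr2 in 10 of 12. Of the 59 genes named for KO testes that passed, 48 did so in at most 6 of these fits and 13 in at most 3. Those 13 were Mirlet7c-1 and Rbp4 (2 of 12) and Dlk1, Cers3, Poteg, Pdgfra, Fabp9, Cald1, 1700029M20Rik, Hsd3b1, Gm10505, Fshr and Rdh11 (3 of 12). Along the first principal component (38.6% of the variance) KO 1 (31.4) and KO 3 (37.0) lay apart from the rest, and KO 2 (8.5) lay beside WT 4 (7.0) and WT 6 (9.7).

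**Figure D3:**
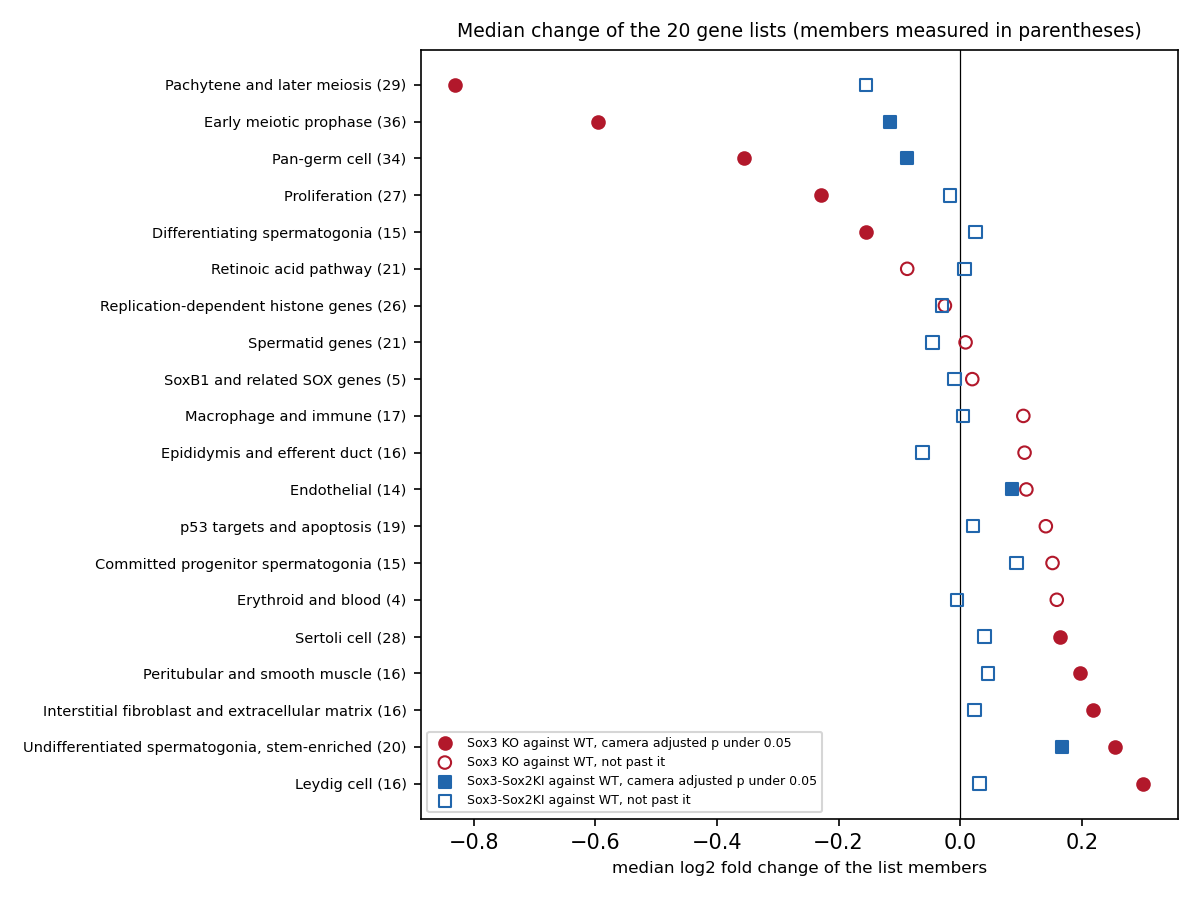
Median log2 fold change of the members of each of the 20 gene lists (number measured in parentheses), for KO against WT (circles) and KI against WT (squares), with filled symbols for a camera adjusted p under the threshold. The pachytene (-0.83) and early meiotic (-0.595) lists are lowest and the Leydig list (0.301) highest in KO testes, and the KI medians lie between -0.155 and 0.167.

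No single gene differed detectably between KI and WT testes. Limma called 0 of 22180, and the count was also 0 in every alternative run, with 1163 genes at an unadjusted p under 0.05 where 1109 arise by chance. The smallest p-values belonged to 5430440P10Rik (-0.57, unadjusted p = 4.66e-05), the protocadherin Pcdhb15 (0.51), Crtac1 (-0.33), 1700091H14Rik (-0.39), 4833407H14Rik (-0.34), Ppcs, an enzyme of coenzyme A synthesis (-0.34), Gm19299 (-0.51), A330049N07Rik (-0.53), the urocortin Ucn2 (-0.53) and the protease Prss29 (-0.34), each with an adjusted p of 0.945. Of these 10 genes 7 lay under the background limit in both groups. Crtac1 had fallen in KO testes, with a change of -0.47 (adjusted p = 0.0149), as had the signal of 4833407H14Rik, which was under the background limit in all groups. Neurog3 in KI testes was 6.17, 5.97 and 6.19, below all WT arrays (6.45 to 6.83) and above all KO arrays (5.09 to 5.53), a difference from WT of -0.51 (SE 0.12). Gfra1 differed by 0.28 (SE 0.07) and Ret by 0.40 (SE 0.10), with every KI array above every WT array for both genes. None of these 3 passed (adjusted p = 0.945 each, unadjusted p = 0.000792, 0.00137 and 0.00177). The Sox3 level of the array labelled KI 1 lay within the WT range, while its Neurog3, Gfra1 and Ret levels lay with the other KI arrays. Since the positions of the Sox3 probes were not known, this Sox3 level cannot settle whether the label is right. Every KI direction given here rests in part on this array, whose label was not checked. For 688 genes (3.1%, where chance gives 2.38%) all 3 KI arrays lay outside the WT range. In simulated data for this comparison, 56.1% of genes changed 1.41-fold in KI testes and 95.8% of those changed 2-fold were recovered. The simulated noise was independent across genes, so recovery in the real arrays may differ. Each run also changed 200 genes, and with fewer changed genes the adjusted threshold would be stricter and recovery lower.

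Among the lists, the stem-enriched spermatogonial genes rose in KI testes with a median of 0.167 (camera adjusted p = 6.48e-05, and adjusted p = 0.158 with an estimated correlation). Adjusted over the list alone, 2 of its 20 members rose, and 1 of the 15 committed progenitor genes fell. The early meiotic list fell with a median of -0.115 (adjusted p = 0.0137, and adjusted p = 0.816 with an estimated correlation), as did the pan-germ cell list with -0.088 (adjusted p = 0.0465, and adjusted p = 0.816 with an estimated correlation). Endothelial genes rose with a median of 0.086 (adjusted p = 0.0465, and adjusted p = 0.816 with an estimated correlation). None of these 4 lists passed by fry, and the other 16 lists did not pass by camera. The early meiotic, pan-germ cell and endothelial calls were lost without WT 2 (adjusted p = 0.0859, 0.232 and 0.0859), without WT 5 (0.0764, 0.228 and 0.228) and without the array labelled KI 1 (0.813, 0.632 and 0.813), whose Sox3 level lay within the WT range. Without WT 1 (0.132 and 0.0633) and without KO 3 (0.0556 each) the pan-germ cell and endothelial calls were lost. The pachytene list became lower without WT 4 (0.00331), WT 6 (0.000426), KI 2 (0.0166) or KI 3 (0.0479), and the epididymis list without WT 3 (0.0425). All fits with 1 array left out were tested at the preset correlation only. Sertoli cell genes became higher without WT 6 (0.0327) or KI 2 (0.0186), and committed progenitor genes without KI 2 (0.0285). Against the KI littermates alone the pachytene list was lower in KI testes with a median of -0.407 (adjusted p = 7.97e-06, and adjusted p = 0.493 with an estimated correlation). In that comparison Sertoli cell genes (0.071, adjusted p = 0.0073, and adjusted p = 0.493 with an estimated correlation) and committed progenitor genes (0.167, adjusted p = 0.0205, and adjusted p = 0.493 with an estimated correlation) were higher, and the endothelial list did not pass (adjusted p = 0.0631). With the WT of the KO litters as control the early meiotic, pan-germ cell and endothelial lists did not pass (adjusted p = 0.413, 0.802 and 0.179), nor did they with the pachytene list as a covariate (0.108, 0.329 and 0.231). Among genes above the median level the endothelial call was lost (0.0603) and the pachytene (0.0122) and proliferation (0.0297) lists were lower, and with array quality weights the pachytene list was lower (0.0219).

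Meiotic, pan-germ cell, differentiating spermatogonial and proliferation genes were higher, and Leydig cell and fibroblast genes lower, in KI than in KO testes as groups by camera with a preset correlation. Of these only proliferation held with the correlation estimated (adjusted p = 0.022 with an estimated correlation). Taken within litter origin, the proliferation difference passed by camera (adjusted p = 7.02e-08) and by fry (0.0415). It did not hold there with the correlation estimated (adjusted p = 0.101 with an estimated correlation). For single genes limma called 0 genes, against 3993 at an unadjusted p under 0.05 and 5 with an intensity trend and robust variance. The smallest p-values belonged to the neurexin Nrxn2 (-0.63, adjusted p = 0.13), the circadian repressor Bhlhe41 (-0.66), Ticrr, which acts in the initiation of DNA replication (0.65), Tgfbi (-0.65), Fam221b (0.54), the transcription factor Tbx1 (0.57), Olfr1181 (-0.79), Cyp2j6 (-0.83), Neurog3 (0.78, SE 0.13, adjusted p = 0.133) and S100a5 (-0.60), with Olfr1181 and S100a5 under the background limit in both groups. In KO testes Tbx1 (-0.59), Ticrr (-0.64) and Fam221b (-0.67) had fallen and Bhlhe41 (0.64) and Tgfbi (0.70) had risen against WT. Without KO 2, 721 genes passed between KI and KO.

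By camera 9 lists differed between KI and KO testes, with the array labelled KI 1 among the KI arrays. Early meiotic genes were higher in KI testes by a median of 0.494 (adjusted p = 4.58e-23, and adjusted p = 0.168 with an estimated correlation) and 25 of 36 were higher when adjusted over the list alone. Pachytene genes (0.701, adjusted p = 1.11e-11, and adjusted p = 0.229 with an estimated correlation) and pan-germ cell genes (0.311, adjusted p = 5.78e-08, and adjusted p = 0.168 with an estimated correlation) were higher too, by 14 and 11 members when adjusted over the list alone. Proliferation genes were higher by 0.221 (adjusted p = 1.11e-11), with 11 of 27 higher when adjusted over the list alone. Differentiating spermatogonia genes were higher (0.207, adjusted p = 0.00589, and adjusted p = 0.168 with an estimated correlation). Lower in KI than in KO testes were the lists of Leydig cells (-0.275, adjusted p = 0.00332, and adjusted p = 0.168 with an estimated correlation) and of interstitial fibroblasts (-0.23, adjusted p = 0.00513, and adjusted p = 0.445 with an estimated correlation). The lists of Sertoli cells (-0.143, adjusted p = 0.0174, and adjusted p = 0.445 with an estimated correlation) and of epididymis (-0.161, adjusted p = 0.0329, and adjusted p = 0.377 with an estimated correlation) were lower as well. The epididymis list mean lay under the background limit in all arrays (4.85 to 5.16). The epididymis call was lost without KO 1 (adjusted p = 0.0554), KO 3 (0.0977) or KI 2 (0.0508), the fibroblast call without KO 1 (0.0554) and the Sertoli cell call without KI 2 (0.161). Taken within litter origin, the Sertoli cell (-0.061, adjusted p = 0.553) and epididymis (-0.134, adjusted p = 0.0834) differences did not pass, and the pachytene (0.257), pan-germ cell (0.168) and Leydig (-0.159) differences were smaller. These 3 passed by camera but not with the correlation estimated (adjusted p = 0.626, 0.445 and 0.41 with an estimated correlation) or by fry (0.665, 0.472 and 0.242). In the plain comparison of KI with KO testes by fry the pachytene (0.0704), Sertoli cell (0.0704), fibroblast (0.156) and epididymis (0.0537) lists did not pass. The stem-enriched list did not differ by camera (-0.139, adjusted p = 0.109), but was lower in KI than in KO testes by fry (0.0444) and among genes above the median level (0.0121), and the committed progenitor and spermatid lists did not differ by camera (adjusted p = 0.916 each) or by fry. The epididymis call was also lost with a new quantile normalization (0.0808). With the pachytene list as a covariate, which removes that list's own difference by construction, the pan-germ cell (0.194), Leydig (0.0714), fibroblast (0.92), Sertoli cell (0.872) and epididymis (0.18) calls were lost, and committed progenitor (0.000536), retinoic acid (0.000536) and endothelial (0.00439) genes became higher in KI testes. Among genes above the median level the histone list was higher (0.251, adjusted p = 0.0122) and the peritubular list lower (-0.148, adjusted p = 0.0109) in KI than in KO testes.

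Because KI and KO mice came from different litters, the effect of each mutation was also taken against its own littermates and the effects were subtracted. No gene passed in this difference (limma, 0 of 22180, smallest adjusted p = 0.847, with 1293 at an unadjusted p under 0.05 and 0 in every alternative run). Lowest by p on the higher side were Mir878 (0.72), Xist (0.80), Neurog3 (0.95, SE 0.19, unadjusted p = 0.00028), Vmn2r75 (0.83) and Alms1-ps2 (1.09), and on the lower side Gm21082 (-1.19), Sh3rf2 (-0.54), Cyp2j6 (-0.98), Olfr1122 (-0.58) and Lypd6 (-0.47). Of these, Mir878, Xist, Vmn2r75, Alms1-ps2 and Olfr1122 lay under the background limit in all groups. For Gfra1 the difference was -0.40 (SE 0.12) and for Ret -0.14 (SE 0.16).

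WT testes of the KI and KO litters differed little in single genes. No gene passed (limma, 0 of 22180, smallest adjusted p = 0.398), with 1174 genes at an unadjusted p under 0.05 where 1109 arise by chance, 1 call with an intensity trend and robust variance, and 50 calls without WT 5. Higher in the KI litters by smallest p were the small nucleolar RNAs Snora34 (0.89), Snora15 (0.76) and Snora28 (0.58), the 5S RNA n-R5s136 (0.67) and Vmn1r178 (0.48). Lower were 8430423G03Rik (-0.61), Olfr983 (-0.82), Hvcn1, a proton channel (-0.32), Gm13582 (-0.43) and Tlcd3a (-0.38), with Vmn1r178, 8430423G03Rik, Olfr983 and Gm13582 under the background limit. Pachytene genes were higher in the WT of KI litters by a median of 0.341 (camera adjusted p = 1.17e-08) and pan-germ cell genes by 0.076 (adjusted p = 0.027), while committed progenitor (-0.123) and Sertoli cell genes (-0.088) were lower (adjusted p = 0.0229 each). None of these 4 lists held with the correlation estimated (adjusted p = 0.628 with an estimated correlation, for each). The pan-germ cell, progenitor and Sertoli cell calls were lost without WT 2 (adjusted p = 0.289, 0.289 and 0.21), WT 4 (0.263, 0.263 and 0.145) or WT 6 (0.266, 0.129 and 0.178). Early meiotic genes (median 0.082) did not pass (adjusted p = 0.054, and adjusted p = 0.787 with an estimated correlation), but were higher by camera with median centring (0.0472), with array quality weights (0.0128) and without WT 1 (0.046), WT 3 (0.0354), WT 5 (0.00389), KO 1 (0.0462), KO 2 (0.014) or the array labelled KI 1 (0.0479). Proliferation genes became higher without WT 3 (0.0354), fibroblast genes without WT 6 (0.0103) and histone genes among genes above the median level (0.00246).

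The changes of KO and KI testes against the 6 shared WT testes correlated at r = 0.318 across genes, which are not independent replicates. Unchanged groups set against the same WT arrays gave a mean of 0.327 in 100 simulations, between -0.462 and 0.827. The covariance was 0.0101 against a simulated mean of 0.00665, a difference of 0.00349, with a simulated upper bound of 0.0227. With each mutant set against its own littermates, so that no array was shared, r was 0.355, within the simulated -0.618 to 0.674, and with each mutant set against the WT of the other litter origin it was -0.139. Of the 1078 genes that passed in KO testes, 936 had the same sign in KI testes, a count that the shared WT arrays alone push up. Those that fell had a median change of -0.563 in KO and -0.101 in KI testes, and those that rose 0.423 and 0.0927. No gene passed in both comparisons by limma. At an unadjusted p under 0.01 there were 2423 genes in KO and 217 in KI testes, and 30 shared genes changed the same way where independent lists give 11.4, an excess that the shared controls alone can give, so it does not show shared change.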

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

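The tests of loss of Sox3, of a lower share of meiotic cells and of the number of control arrays were chosen only after the results they bear on were seen, as was the fit with the pachytene list as a covariate.

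Among the 6 WT arrays, 131 tests for a single array far from the others gave 3 such arrays, where chance gives about 6.6 (about 1 in 20 groups). The spermatid list mean was 5.33 in WT 3, a gene of the early meiotic list was 6.23 in WT 6 and the testis histone gene H2ac1 was 13.48 in WT 5, each far from the other WT arrays. In the 17824 transcript clusters with no or several gene symbols, 0 were called by limma in KO testes and 0 in KI testes, with 1886 at an unadjusted p under 0.05 in KO testes. These clusters were listed because they lay outside the comparisons. The histone clusters described below were adjusted together with the 22180 genes tested, so their calls can differ from this count.

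The effects of the KI and KO mutations, each taken against its own littermates, differed for 8 lists by camera's test of the difference. The median difference of KI minus KO effect was 0.44 for early meiotic genes (adjusted p = 3.41e-17), 0.26 for pachytene genes (0.00296), 0.17 for proliferation (7.02e-08), 0.17 for pan-germ cell genes (0.000259), 0.22 for differentiating spermatogonia (0.000526) and 0.22 for the retinoic acid pathway (0.0105). It was -0.32 for interstitial fibroblasts (0.000228) and -0.16 for Leydig cells (0.0412). None held with an estimated correlation (in that order, adjusted p = 0.248, 0.626, 0.101, 0.445, 0.133, 0.245, 0.523 and 0.41 with an estimated correlation), and proliferation held by fry (0.0415). Among genes above the median level the retinoic acid call was lost (0.243), and the stem-enriched (0.00349) and peritubular (0.0403) lists gained one. With 1 array left out the Leydig call was lost without WT 1, WT 4, WT 5, KO 1, KO 3 or KI 2 (0.062 to 0.342), the pachytene call without WT 5 (0.858) or KO 3 (0.121), the pan-germ cell call without WT 5 (0.0561) and the retinoic acid call without the array labelled KI 1 (0.0562), whose Sox3 level lay within the WT range. Committed progenitors gained a call with array quality weights (0.036) and without WT 3 (0.0252), WT 5 (0.00274) or KI 2 (0.00951), macrophage genes with the weights (0.0189) and without WT 3 (0.022), WT 5 (0.0257), KO 2 (0.0199) or the array labelled KI 1 (0.0218), and epididymis genes without WT 3 (0.022).

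Of the 84 splits of the KO and WT arrays into 3 and 6, 1, the real split, gave as many as 1078 genes, and the highest other gave 429. The real split thus gave the most calls, but 1 of 84 is the smallest share this test can give. The splits also mix WT arrays of both litter origins, so the test cannot separate genotype from litter origin or other structure among the arrays. The split with 429 calls set WT 1, WT 2 and WT 5 apart, the WT arrays lowest on the first principal component (-16.9, -22.8 and -23.2). Its other side held WT 3, WT 4, WT 6 and the 3 KO arrays. The KO difference thus feeds this count, which cannot be read as structure among the WT arrays alone. Every split reaches a real count of 0, so for the next comparisons this test says nothing about chance. For KI against WT the real count was 0 and 84 of 84 splits reached it, and the highest other, 129, set WT 4, WT 6 and the array labelled KI 1 apart, a structure of the samples that does not follow the genotypes. For the difference of the mutant effects the real count was 0, reached by 100 of 100 regroupings, the highest other being 3. For KI against KO and for the WT litters 10 splits are too few for a share under 0.05, and in both the real count was 0 and the highest other 0, a count reached by 10 of 10.

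Early meiotic genes were lower in KO testes, and the pachytene list mean, read here as the stage of the first wave, also varied among WT testes. Stage itself was not measured. From the WT slope of the early meiotic on the pachytene list (0.247) and the KO shift of the pachytene list (-0.888), a shift of -0.219 was predicted (95% interval -0.322 to -0.116), and -0.672 was observed, which argues against the variation seen among WT testes as the whole cause. The prediction runs below the lowest WT array for KO 1 and KO 3, so a delay beyond the WT range stays open. Loss of Sox3 stays an open hypothesis: the list mean was lower in 3 of 3 KO arrays than in every WT array, but this restates the decrease already seen and lends it no support. Whether fewer cells or less RNA per cell lay behind it was not tested.

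Neurog3 fell and Gfra1 and Ret rose in KO testes. With the pachytene list as a covariate all 3 kept their direction and an unadjusted p under 0.05. This fit cannot decide on stage as a cause, since the covariate was itself lower in KO testes (-0.888). KO 1 and KO 3 lay below every WT array in it, so the fit extends beyond the WT range. In that fit Neurog3 moved from -1.29 (SE 0.12) to -1.65 (SE 0.11, adjusted p = 0.000205). Gfra1 moved from 0.70 (SE 0.07) to 0.63 (SE 0.10, adjusted p = 0.243) and Ret from 0.71 (SE 0.10) to 0.41 (SE 0.10, adjusted p = 0.531). The adjusted calls of Gfra1 and Ret ended with a smaller change for Ret and a larger error for Gfra1, in a fit that called 1 gene in all. A lower share of meiotic cells would raise other transcripts alike, and Neurog3 at -1.29 lay far below the 5th percentile (-0.08) of 107 somatic list members, with 1 member, Hsd3b6 at -1.74, lower still. For Gfra1 and Ret that explanation stays open, since their smaller lower bound, 0.51, did not exceed the 95th percentile of the somatic members (0.62), 4 of those members lay above each, and a change in the spermatogonia themselves remains an untested hypothesis.

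Littermate controls left 2 KO calls of 1078. Fewer control arrays stay open as a cause: the 3 WT arrays of the other litter origin gave 1345 calls, but those arrays also differ in the pachytene list, and leaving out 1 control left 36 (WT 1), 35 (WT 2), 18 (WT 3), 1578 (WT 4), 32 (WT 5) or 1748 (WT 6) calls. Simulated recovery of 1.41-fold changes was 52.8% with 6 WT arrays and 22.8% with 3 littermates. For 2-fold changes it was 96.5% and 94%. The simulated changes were given to genes drawn at random. The largest real decreases were in genes that varied more, such as Fabp9 (SE 0.73) and Cers3 (SE 0.61). Over all genes the median 95% interval reached 0.22 to either side, so the simulation does not describe the loss of these larger changes. The noise in the simulation was independent across genes, so these rates may not carry over to the real arrays. Whether uneven stage among the KO littermates lay behind it cannot be told apart from other causes: with the pachytene list as a covariate 1 call was left against littermates, but the same covariate also left 1 call with all 6 WT arrays as control, so that the fit could not show a gain. A difference between litter origins also stays open, untested.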

How the results depend on the processing

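The fits with the pachytene list as a covariate, and the widened histone list, were chosen only after the results were seen, and the other alternatives were planned. KI against WT gave 0 genes in every setting run. Among named genes 1949 values stayed on their side of the threshold (those that did not pass in either fit with any sign), 44 gained a call, 730 lost one and 2 with a call turned sign, and among list tests 2076, 68, 130 and 4 did. The replicate numbers did not pair the arrays: 9 correlations of same-numbered arrays were between -0.03 and 0.16, with 3 above 0.1. The replicate block leaves WT 4, WT 5 and WT 6 without a partner, so it also changes the control to WT 1, WT 2 and WT 3. With it KO against WT had 1468 calls, KI against WT 0 and KI against KO 247 (202 higher, 45 lower). Of 110 named genes 22, Sox2 and Sox1 among them, lay under the background limit (5.33) in all groups and 28 in at least 1, and the KO level of Neurog3 was 5.34. The cause was not tested for the values given next, except that the 1.5-fold limit is stricter by construction.

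KO against WT (1078 calls) had 315 with the 1.5-fold limit, 2459 among genes above the median level, 2048 with an intensity trend and robust variance, 2 with littermates alone or with litter origin as a covariate (the same model), 30 with the 9 arrays of mutant and WT, 0 with 6 arrays, 1 with the pachytene covariate, 1 with it and littermates, and between 2 and 2323 with 1 array left out. The KO change of Sox3 was -0.69 but not past the threshold with littermates alone (adjusted p = 0.0983), with litter origin as a covariate and with 6 arrays (adjusted p = 0.469), and -0.78 in both pachytene fits (adjusted p = 0.304 and 0.414), against -0.70 to -0.66 with 1 array left out, where it passed in 10 of 12. KI against KO (0 calls) had 57 among genes above the median level, 5 with the trend and robust variance, 1 with the pachytene covariate, and 0 to 721 with 1 array left out (721 without KO 2, 1 without the array labelled KI 1). The WT litters had 1 with the trend and robust variance and 0 to 50 with 1 array left out (50 without WT 5). Called in both KO and KI were 30 genes at an unadjusted p under 0.01.

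Of lists, KO against WT had 1 past the threshold with an estimated correlation (10 by camera), KI against KO 1 (9 by camera), and the difference of effects 0, and 1 by fry (8 by camera). By fry, KO against WT kept all the lists called by camera except interstitial fibroblasts. KI against WT (4 by camera) had 1 with the WT of the other litter origin, 7 with 6 arrays, 1 with the pachytene covariate, 2 with it and littermates, 0 with an estimated correlation, 0 by fry and 1 to 7 with 1 array left out. The WT litters (4 by camera) had 0 with an estimated correlation, 0 by fry and 1 to 6 with 1 array left out. With the pachytene covariate Poteg in KO testes turned to 0.01, also with littermates, and 3 list results turned direction: committed progenitors in KO testes became lower (adjusted p = 0.00496, and 0.00565 with littermates), interstitial fibroblasts in KO testes turned only relative to other genes, with a positive median and without passing (adjusted p = 0.96), and interstitial fibroblasts in KI testes with littermates turned (adjusted p = 0.000268).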

Other observations

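The X-linked genes, the small nucleolar RNA genes and the Leydig gene below were looked at after the main results were seen.

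Of 899 X-linked genes among 21994 with a known chromosome (4.09%), 26 were among 556 genes that rose in KO testes (4.68%) and 17 among 520 that fell (3.27%), with no difference by Fisher's exact test (p = 0.277, over genes, which are not independent). The X-linked genes that rose included Heph, a copper-dependent iron oxidase (0.77), the glypican Gpc3 (0.47), the actin crosslinker Flna (0.43), the chromatin remodeller Atrx (0.36) and the Sertoli cell homeobox gene Rhox8 (0.34). Those that fell included Gm648 (-1.02), Fmr1nb (-0.77), the gap junction gene Gja6 (-0.70), Ccnb3, a cyclin of meiotic cells (-0.69), and, at levels near background, Xist (-0.51, adjusted p = 0.0353). The median change was 0.088 for X-linked and 0.041 for autosomal genes.

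Of the Leydig cell genes Hsd3b1 rose in KO testes. Hsd3b6, an isoform of adult Leydig cells, was 6.19 ± 1.21 (SD, n = 3) in KO and 7.93 ± 1.13 (SD, n = 6) in WT testes, a difference of -1.74 (SE 0.63) that did not pass (adjusted p = 0.115). Hsd3b6 also differed by 1.56 (SE 0.60) between the WT testes of the KI and KO litters, without passing (adjusted p = 0.891). Crtac1, an extracellular matrix protein gene that fell in KO testes, was 5.47 to 5.63 there, 5.61 to 5.74 in KI and 5.96 to 6.05 in WT testes, and its KI difference of -0.33 did not pass.

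With 30 clusters that name several histone genes added to the histone list, 6 of 56 clusters fell, 1 rose and 49 did not pass in KO testes, with a median of -0.106. These calls were adjusted over the 22180 genes tested and the 30 clusters together. The 0 calls among the clusters with no or several symbols, given above, came from a different set of tests. The wider list fell by camera (p = 0.00121) and not with the correlation estimated (p = 0.106 with an estimated correlation).

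Small nucleolar RNA genes were looked at because members of this class led the comparison of WT litters, so their counts are no independent test of it. Of 73 measured, 57 (78.1%) were higher in the WT of KI litters, with a median of 0.14, and the class did not pass with the correlation estimated (p = 0.103 with an estimated correlation). Array means were 8.73 to 8.74 in WT 1, WT 2 and WT 3 and 8.53 to 8.64 in WT 4, WT 5 and WT 6. KI testes had 13 of 73 higher than in their own littermates (17.8%), with a median of -0.13 (p = 0.152 with an estimated correlation) and means of 8.74, 8.56 and 8.52. That decrease is measured against the same high arrays WT 1, WT 2 and WT 3, so it is no separate finding. In KO testes 50 of 73 were higher than in littermates, with a median of 0.08, without passing by camera.

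Genes with a p under 0.01 in KO testes against their own littermates numbered 438. In KI testes against their own littermates 330 of them (75.3%) had the same sign, within the 22.4% to 78.2% that unchanged KI testes gave in simulation. Their median change was 0.482 in KO and 0.0936 in KI testes in the KO direction, where unchanged KI testes gave -0.103 to 0.105.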
